A study of Homo sapiens with 12 samples.

How the data were processed

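RNA of 2 human lung cancer lines was hybridised to Affymetrix whole-transcript arrays. The lines are A549 and HTB56, each unselected (0R) or after 3 rounds of selection in mice for lung colonisation (3R), with 3 arrays per group and 12 in all. Per the labels' protocols, total RNA was extracted with a column kit and labelled with the Affymetrix whole-transcript labelling workflow. The labels give all samples as untreated with respect to 5-azacytidine. The deposited table holds log2 values made by RMA in Affymetrix Expression Console, per the submitters' processing notes, and the versions are not given in the sources used here. RMA corrects background, quantile-normalizes the arrays to a common distribution and summarises the probes of a set, so small differences of a dim gene are compressed toward background and a uniform shift of all mRNA would be removed. Scanner files were not used here, so the background correction, the normalization of probes and a slide effect could not be varied. The table held 33297 probe sets with 0 missing values, 0 unused columns and 0 pairs of identical arrays.

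Probe sets were named with a table of platform annotation. Of the 33297, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed and so remained unnamed. The Entrez identifier of 19429 matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table also gave the order of neighbouring genes, and no coordinates are printed. The 24 probe sets of Y-linked genes and XIST were left out, which left 18394 genes. A probe set was kept where it lay above the 20th percentile of its array (3.48 on average) on at least 3 of the 12 arrays, and each gene was represented by its brightest probe set over all arrays, which gave 16922 genes. Of the 692 tested genes with several probe sets, 12 in A549 and 116 in HTB56 had a called probe set, and 0 had probe sets called in opposite directions. Probe sets with several symbols or none entered no named result.

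All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). One mean per group was fitted over all 12 arrays, which share an estimate of the spread. The comparisons were 3R against 0R in each line, the difference of these changes (HTB56 minus A549), and unselected HTB56 against unselected A549. Calls of both lines were compared with the overlap of independent lists. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists, with an estimated correlation and fry beside it. The lists, the tests, the named-gene rule and the alternatives were set before the data were examined. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

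The lists covered epithelial junction and keratin genes, mesenchymal genes, matrix proteases and their inhibitors, integrins and laminins, chemokines and inflammatory cytokines, interferon response, antigen presentation, cell cycle, hypoxia and glycolysis, NRF2 targets and xenobiotic metabolism, p53 targets, cholesterol synthesis, unfolded protein and amino acid stress, TGF-beta and BMP, Wnt and Notch signalling, growth factor receptors and ligands, HOX clusters, other developmental transcription factors, DNA methylation and Polycomb machinery, cancer-testis antigens, lung epithelial lineage, stem cell-associated genes, metastasis suppressors, ribosomal proteins, immediate early and heat shock genes, and markers of fibroblasts, endothelium and leukocytes. Genes were named by rule: in each line the 10 largest rises and 10 largest falls among called genes whose 3 selected arrays do not overlap the 3 unselected ones, leaving out non-coding, pseudogene and olfactory receptor symbols and the like; the leading genes changed the same or opposite ways in both lines; the 10 largest differences each way between unselected lines; up to 2 called members per list, direction and line; and CDH1, VIM, EPCAM, ZEB1, MKI67, EZH2, DNMT1, DNMT3A and DNMT3B. Genes of later hypotheses are named as chosen afterwards.

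The groups share replicate numbers, and their meaning is not given in the sources used here. Deviations from the group mean correlated across genes at 0.149 to 0.469 between arrays with the same number and at -0.342 to 0.166 between arrays with different numbers, and 12 of 12 arrays correlated best with their own number. The numbers therefore pair the samples, from the data, and a fit with the replicate number as a block is given beside the comparisons and gene lists where it changes a call or moves a count of calls by over 1.5 times.

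Alternatives were the filter on dim probe sets, the choice of probe set per gene, median centring or cyclic loess on top of RMA, a fit on the 6 arrays compared, the block, eBayes with trend and robust settings, array weights, a threshold of 0.01, a treat test against a fold of 1.2, the set test, and leaving out each array in turn. Leaving out the 4 arrays numbered 3 and a block shared by both lines were added afterwards. Other splits of the arrays were counted, at most 100 per result. A simulation held 16922 genes, of which 67, 67 and 66 in each line were changed 1.5-fold, 2-fold and 4-fold. There the A549 comparison recovered 44.8% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, and 9.14% of its calls were unchanged genes. For HTB56 these shares were 59.7%, 86.6%, 100% and 4.09%, and for the difference between lines 24.6%, 77.6%, 98.5% and 9.8%. A far smaller part of the genes changed in the simulation than the 19.5% called in the real HTB56 comparison. Recovery at an adjusted p depends on that part, so these rates need not hold for the real comparisons. In simulated data the set test called the list that was shifted and 0 of the others, and a search for runs of neighbouring genes found 1 run that held the 60 genes shifted together and 0 runs without them. The simulated noise was drawn independently for each gene and array. In the real data the list shifted here, cholesterol synthesis, had an estimated correlation of 0.465. False calls from correlated genes or paired arrays were therefore not tested by the simulation.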

Results

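Messenger RNA was measured on 12 Affymetrix whole-transcript arrays in A549 and HTB56, both established human lung cancer lines. A549 is a lung adenocarcinoma line, and HTB56 is also known as Calu-6. Each line was measured as the unselected parent (0 rounds, here A0R and H0R) and as the line recovered after 3 rounds of selection in mice for lung tumour nodules after injection into a vein (A3R and H3R), with 3 arrays in each of the 4 groups. All values are log2 RMA signals, and the array medians lay between 5.55 and 5.67. Signals of 2 arrays of 1 group correlated across probe sets with r between 0.988 and 0.995, arrays of the 2 lines with r between 0.949 and 0.961. A gene was called at a limma adjusted p below 0.05 among 16922 genes tested, and the number of arrays limits the precision. The labels do not say whether the 3 replicates were separate cultures, so each p measures only the spread between these samples.

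The comparison of A3R with A0R asks which transcripts differ between selected and unselected A549 cells. Selected A549 cells carried more mRNA of SYT13, a synaptotagmin of membrane trafficking, which stood at 5.71 ± 0.58 (SD, n = 3) in A0R and 8.42 ± 0.21 in A3R, a rise of 2.70 on the log2 scale (SE 0.22, limma adjusted p = 1.26e-05). CDH2, which encodes N-cadherin, rose from 5.62 ± 0.43 to 7.53 ± 0.42 (log2 change 1.90, SE 0.21, limma adjusted p = 0.000164), while CDH1, which encodes E-cadherin, went from 9.53 ± 0.02 to 8.68 ± 0.31 and so fell by 0.85 (SE 0.15, adjusted p = 0.00922). NTS, the precursor of the secreted peptide neurotensin, fell by 4.20 (SE 0.29, adjusted p = 2.73e-06), from 8.43 ± 0.57 to 4.23 ± 0.63. F5, which encodes coagulation factor V, fell by 2.65 (SE 0.14, adjusted p = 4.68e-07). The neutrophil-attracting chemokine gene CXCL1 rose from 8.63 ± 0.19 to 10.30 ± 0.08 (log2 change 1.67, SE 0.15, adjusted p = 2.37e-05).

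Of the 16922 genes, 284 were called in A549, 158 higher and 126 lower in A3R, and 87 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 1678 genes. The 3 selected and 3 unselected arrays did not overlap for 12.7% of genes, where chance gives 10% for exchangeable arrays. That 10% leaves the pairing by replicate number out of account. Besides SYT13, CDH2 and CXCL1, the 10 largest rises were those of DPYSL3 (2.38), TNFSF15 (1.79), GASK1B (1.73), EFEMP1 (1.64), SERPINA3 (1.59), CXCL5 (1.58) and FAM133A (1.53). After NTS and F5, the largest falls were those of LIN7A (-2.64), SCN9A (-2.12), SLC17A3 (-2.07), NPY1R (-1.97), SLPI (-1.96), FGB (-1.88), ADGRL2 (-1.86) and ADH6 (-1.81), which read 3.21 in A3R, under the 20th percentile of 3.48, so its size depends on background. SCN9A encodes a voltage-gated sodium channel, NPY1R a receptor of neuropeptide Y, SLPI a secreted protease inhibitor and FGB a chain of fibrinogen.

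Chemokine and inflammatory cytokine genes rose as a group in selected A549 cells: 11 of 35 tested were called higher and 0 lower, and 16 when adjusted over the list alone (camera adjusted p = 1.23e-16). CXCL5 rose from 10.43 ± 0.13 to 12.01 ± 0.43, CXCL8 by 1.48 (SE 0.22) and PTGS2, which encodes an enzyme of prostaglandin synthesis, by 0.85 (SE 0.16). Interferon response genes also rose as a group, with 4 of 41 called higher and 0 lower, and 9 when adjusted over the list alone (camera adjusted p = 1.81e-10, median log2 change 0.28). Of the called members, IFIT1 lost its call without any 1 of the 6 A549 arrays (limma adjusted p from 0.057 to 0.181), H0R replicate 2 or H3R replicate 3. SAMD9 lost its call without A0R replicate 1 or 2 or A3R replicate 1 or 2 (0.0563 to 0.0684). Among integrins and laminins, 4 of 34 were called higher and 0 lower, the same 4 over the list alone (camera adjusted p = 2.38e-05), led by the basement membrane collagen genes COL4A6 (1.42, SE 0.13) and COL4A5 (1.05, SE 0.11). In the mesenchymal list CDH2 was the 1 of 38 genes called, and 7 were called higher when adjusted over the list alone (camera adjusted p = 0.000312). VIM, the vimentin gene of that list, was 11.35 ± 0.10 in A0R and 11.28 ± 0.04 in A3R (adjusted p = 0.92). EPCAM, ZEB1, MKI67, EZH2, DNMT1 and DNMT3A were not called in A549 either. With the replicate block 6 mesenchymal and 8 interferon genes were called higher and 0 lower. These 4 lists kept their calls with an estimated correlation, at adjusted p = 0.00442, 0.00276, 0.0222 and 0.0204 in the order given. Camera called 8 lists in A549, and 2 of 10 splits of its arrays gave as many, the grouping by selection among them. Chance is therefore not excluded for the number of lists called.

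Lung epithelial lineage genes rose in A549 at a camera adjusted p of 0.000325, with 2 of 32 called higher, CEACAM6 (1.31, SE 0.18) and TFF1 (0.93, SE 0.18), and 2 over the list alone, but this call was lost with an estimated correlation (adjusted p = 0.119). Antigen presentation genes lay higher (adjusted p = 0.0412, with 0 of 22 members called and 1 over the list alone), cell cycle genes lower (adjusted p = 0.0372, with 0 of 52 called) and NRF2 targets and xenobiotic metabolism genes lower (adjusted p = 0.0287, with CYP4F11 the 1 of 40 called). With an estimated correlation the adjusted p of these 3 lists was 0.614, 0.705 and 0.705. The antigen presentation call was lost without A0R replicate 3 (0.246) or A3R replicate 1 (0.37), the cell cycle call without A0R replicate 1 (0.237) or 3 (0.133) or A3R replicate 2 (0.148) or 3 (0.281), and the NRF2 call without A0R replicate 1 (0.176) or A3R replicate 3 (0.522). The epithelial junction and keratin list split, with KRT19 (1.14, SE 0.14) and CLDN4 (1.03, SE 0.16) higher, CDH1 and AP1M2 lower, and no shift of its 40 genes (camera adjusted p = 0.894). The call of AP1M2 was lost without A0R replicate 1 or 2, any A3R array, or H3R replicate 1 or 2, at adjusted p from 0.0534 to 0.158. That of TFF1 was lost without A0R replicate 1 (0.082) or 3 (0.051) and without A3R replicate 2 (0.052) or 3 (0.0717), and that of CYP4F11 without A0R replicate 1 (0.0513). TGF-beta and BMP signalling genes had 3 called higher, among them PMEPA1 (1.23, SE 0.19), and 1 lower of 41 (adjusted p = 0.62). Growth factor receptors and ligands had 2 higher and 4 lower of 49 (adjusted p = 0.588), with ERBB3 (-1.02, SE 0.12) and IGFBP2 (-1.09, SE 0.11) among the lower. With the replicate block 5 genes were higher and 3 lower in the TGF-beta and BMP list, and 0 higher and 2 lower in each of the cell cycle and NRF2 lists.

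The other lists gave no camera call in A549. Matrix proteases and their inhibitors had 1 higher and 1 lower of 39 (adjusted p = 0.336), Wnt signalling genes 2 and 1 of 47 (0.894), stem cell-associated genes 2 and 1 of 25 (0.894), metastasis suppressors 1 and 1 of 25 (0.894) and other developmental transcription factors 2 and 0 of 139 (0.894). Of the unfolded protein list 1 of 32 was higher (0.194), and of the DNA methylation and Polycomb list DNMT3B was the 1 of 43 called, at -0.65 (SE 0.11, list p 0.25). Limma called 0 members among 24 cancer-testis antigens (0.894), 27 HOX genes (0.845), 28 Notch genes (0.845), 29 p53 targets (0.0938), 37 hypoxia and glycolysis genes (0.0938), 19 cholesterol synthesis genes (0.309), 48 ribosomal protein genes (0.205) and 33 immediate early and heat shock genes (0.205). At an unadjusted p below 0.05 these 8 lists had 1, 4, 4, 3, 6, 1, 0 and 4 members in that order, the antigen presentation list 4 and the cell cycle list 5. Of markers of cells a mouse lung could leave behind, C1R was the 1 of 14 fibroblast markers called higher (list p 0.102), with 0 of 14 endothelial (0.4) and 0 of 19 leukocyte markers (0.76), and 0 and 2 of these at an unadjusted p below 0.05. With the replicate block the counts higher and lower were 4 and 1 for proteases, 2 and 2 for Wnt, 1 and 2 for metastasis suppressors, 2 and 4 for other developmental factors and 1 and 2 for the unfolded protein list. They were 1 and 0 for HOX genes, 1 and 1 for hypoxia, 2 and 0 for fibroblast markers, and 0 and 1 each for Notch, p53, cholesterol, cancer-testis and leukocyte lists. The median and mean of the Notch list in A549 differed in sign (0.03 and -0.04).

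With the replicate number as a block, 526 genes were called in A549, 272 higher and 254 lower, and 273 of the 284 were among them. The count was 167 without A0R replicate 1, 174 without A0R replicate 2 and 175 without A3R replicate 2. A0R replicate 2 also stood apart from the other A549 arrays on genes of the other line: for 28 genes bright in both HTB56 groups and dim in A549, it lay above the A549 median by a median of 0.84, against -0.15 to 0.07 on the other 5 arrays. Of these 28 genes limma called 0 between A3R and A0R, and 4 had an unadjusted p below 0.05. Without that array the change was 2.51 for SYT13, 1.71 for CDH2, 1.64 for CXCL1, -2.55 for F5 and -4.39 for NTS.

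**Figure D1:**
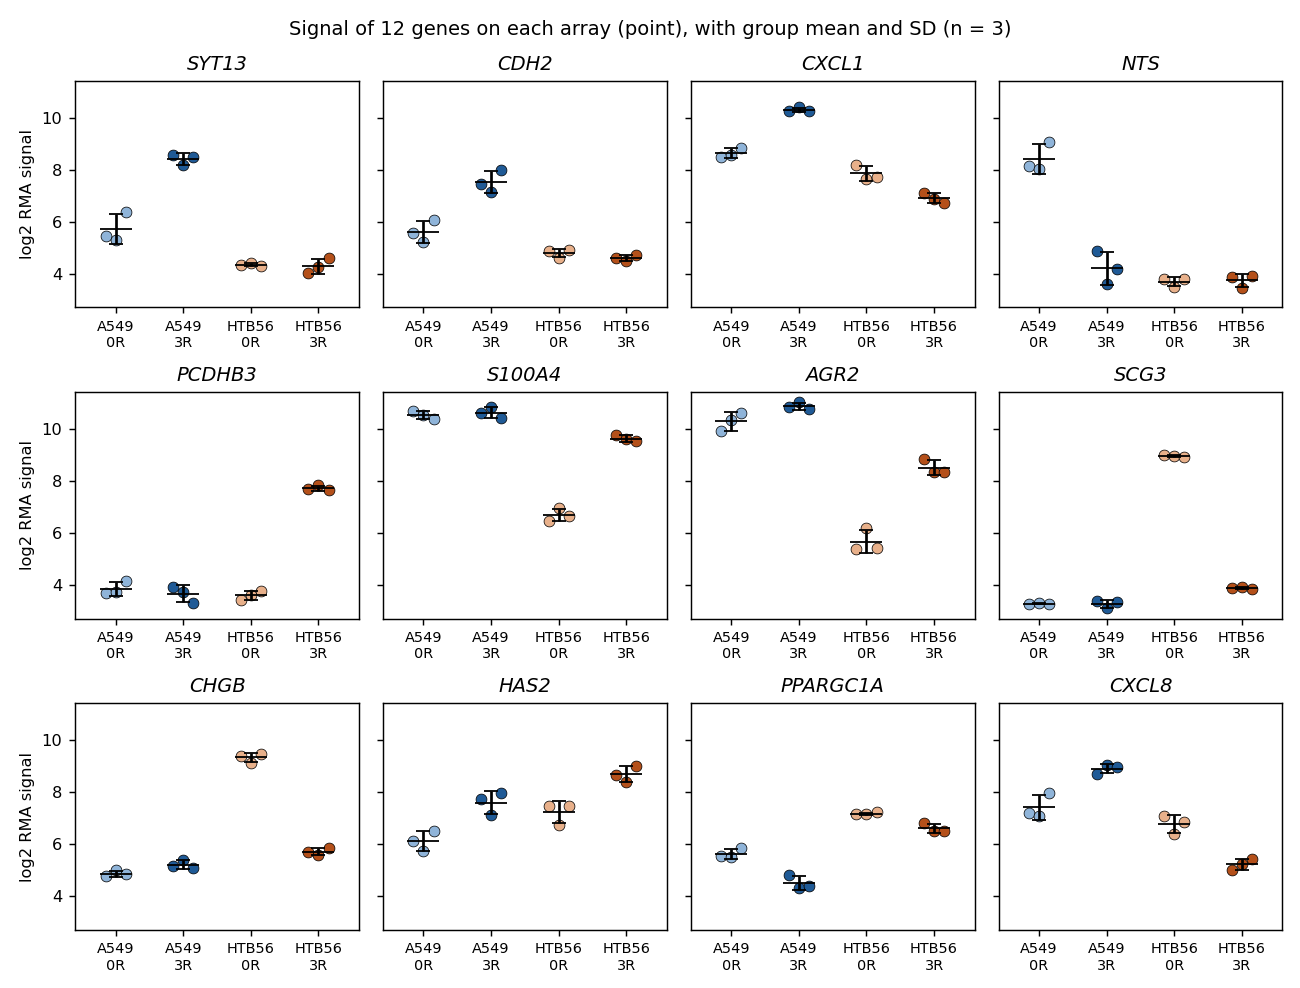
Each panel plots 1 gene, with log2 RMA signal on the vertical axis and the 4 groups on the horizontal axis; points are single arrays and the bar is the mean with its SD (n = 3). SCG3 stood at 8.96 in H0R and 3.90 in H3R, whereas both A549 groups lay near 3.30, and CXCL8 moved by 1.48 in A549 and by -1.54 in HTB56.

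The comparison of H3R with H0R asks the same question in HTB56. The largest falls in selected HTB56 cells included 4 genes of secretory granules and vesicle release. SCG3, which encodes secretogranin III, fell by 5.06 (SE 0.10, limma adjusted p = 2.05e-13), from 8.96 ± 0.05 (SD, n = 3) to 3.90 ± 0.05. CHGB, the chromogranin B gene, fell by 3.62 (SE 0.12), SCG2, the secretogranin II gene, by 3.61 (SE 0.14), and RAB3C, a small GTPase gene of vesicle release, by 3.76 (SE 0.14). The calcium-binding protein gene S100A4 rose by 2.94 (SE 0.14, adjusted p = 3.89e-09), from 6.69 ± 0.24 to 9.63 ± 0.12, and was 10.53 ± 0.15 in unselected A549. PCDHB3, a clustered protocadherin gene, rose by 4.11 (SE 0.16, adjusted p = 7.41e-10) from 3.62 ± 0.18 to 7.72 ± 0.09. AGR2, which encodes a protein of the endoplasmic reticulum of mucus-secreting epithelia, rose by 2.83 (SE 0.22, adjusted p = 4.52e-07).

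In HTB56 3298 of 16922 genes were called, 1452 higher and 1846 lower in H3R, and 508 changed at least 2-fold, 166 higher and 342 lower. At an unadjusted p below 0.05 there were 4901 genes, and the selected and unselected arrays did not overlap for 34.3% of genes, where chance gives 10% for exchangeable arrays. The remaining largest rises were those of PCDHB2 (3.33), DIO2 (3.00), TSPAN8 (2.82), COLEC10 (2.74), GPC6 (2.46), CD96 (2.45) and NRK (2.43). The remaining largest falls were those of MFNG (-3.64), FSTL5 (-3.63), DIAPH2 (-3.42), TMEM145 (-3.34), UGT8 (-3.34) and NSG2 (-3.25). FSTL5 and DIAPH2 read 3.24 and 3.27 in H3R, and NRK 3.45 in H0R, under the 20th percentile of 3.48, so the size and rank of their changes depend on background. MFNG encodes a glycosyltransferase that modifies Notch receptors, and DIAPH2 a formin that nucleates actin filaments.

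Epithelial junction and keratin genes lay higher as a group in selected HTB56 cells, with 8 of 40 called higher and 1 lower (camera adjusted p = 0.0119, median log2 change 0.0985). Adjusted over the list alone, 10 were higher and 1 lower. The list call was lost with an estimated correlation (camera adjusted p = 0.179). That correlation was 0.00375, under the preset 0.01, so a higher correlation did not end the call. The desmosome genes DSP, from 4.30 ± 0.15 to 6.54 ± 0.09 (log2 change 2.24, SE 0.18), and DSG2 (1.95, SE 0.10) led the rise, EPCAM rose by 1.02 (SE 0.23), and KRT7 was the member that fell (-0.91, SE 0.14). CDH1 was 4.55 ± 0.16 in H0R and changed by -0.05 (adjusted p = 0.9). Cholesterol synthesis genes fell as a group, with 9 of 19 called lower and 1 higher, and 12 and 1 over the list alone (camera adjusted p = 0.00278), but not with an estimated correlation (adjusted p = 0.656). INSIG1, a sterol-regulated inhibitor of that pathway, fell by 1.40 (SE 0.16) and SQLE by 0.87 (SE 0.10), while NSDHL rose by 0.85 (SE 0.12). NRF2 targets and xenobiotic metabolism genes lay lower, with 9 of 40 called lower and 3 higher, and 10 and 4 over the list alone (camera adjusted p = 0.0385); with the replicate block the adjusted p was 0.0855 and with an estimated correlation 0.75. ABCC2, an efflux transporter gene, fell by 2.12 (SE 0.19) and CYP1B1 by 1.90 (SE 0.19). Leaving out 1 array also ended the call of the NRF2 list, at adjusted p = 0.198 without H0R replicate 2, 0.0975 without H3R replicate 2, 0.11 without H3R replicate 3 and 0.057 without A3R replicate 1. Camera called 3 lists in HTB56, and 5 of 10 splits of its arrays gave as many, the grouping by selection among them. Chance is therefore not excluded for the number of lists called.

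Mesenchymal genes changed in both directions in HTB56. Of 38 tested, 12 were called lower and 6 higher (camera adjusted p = 0.287), with CDH11 (-2.60, SE 0.16) and LOX (-2.02, SE 0.20) lower and S100A4 and SNAI2 (1.17, SE 0.24) higher. VIM was 11.97 ± 0.06 in H0R and 12.14 ± 0.01 in H3R (adjusted p = 0.241). ZEB1 was called higher, at 0.46, a call lost without H0R replicate 1 (limma adjusted p = 0.051) or H3R replicate 3 (0.0569). Matrix proteases and their inhibitors had 7 higher and 9 lower of 39 (0.445), among them the collagenase gene MMP1 (1.71, SE 0.23) and the gelatinase gene MMP2 (-2.35, SE 0.12). TGF-beta and BMP signalling genes had 6 higher and 12 lower of 41 (0.333), with BMP2 at 1.31 (SE 0.18) and ID2 at -1.30 (SE 0.17). Interferon response genes had 1 higher and 9 lower of 41 (0.0624), with IFI44L at -1.40 (SE 0.13). Wnt signalling genes had 4 higher, FZD8 first at 1.62 (SE 0.10), and 5 lower, LEF1 first at -1.52 (SE 0.22), of 47 (0.966). Notch signalling genes had 1 higher, JAG1 at 1.12 (SE 0.10), and 5 lower of 28 (0.799), with a median of 0.04 and a mean of -0.14. Growth factor receptors and ligands had 6 higher and 8 lower of 49 (0.94), and KIT, a receptor tyrosine kinase gene, fell by 3.11 (SE 0.20) to 3.46, also under that percentile of 3.48. With the replicate block 4 Notch genes were higher and 7 lower, and 2 interferon genes higher and 12 lower.

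HOX cluster genes had 3 higher and 4 lower of 27 in HTB56 (camera adjusted p = 0.966), with HOXB2 at 1.96 (SE 0.15) and HOXD10 at -2.15 (SE 0.14). Other developmental transcription factors had 7 higher and 14 lower of 139 (0.94), with PAX6 (-2.05, SE 0.14) and SOX2 (-1.67, SE 0.20) lower. Cancer-testis antigens had 3 higher and 1 lower of 24 (0.246), with MAGEC2 at 1.94 (SE 0.14), PRAME at 1.35 (SE 0.10) and DDX53 at -3.05 (SE 0.17). The DNA methylation and Polycomb list had 3 higher and 10 lower of 43 (0.126), with MBD4 (-0.64, SE 0.10) and DNMT3A (-0.40) among the lower. The DNMT3A call was lost under 2 of 24 alternatives. DNMT1 was 9.83 ± 0.07 in H0R and 9.78 ± 0.10 in H3R (adjusted p = 0.824), and DNMT3B and EZH2 were not called. Stem cell-associated genes had 7 higher and 4 lower of 25 (0.245), with CD9 at 1.77 (SE 0.13), and lung epithelial lineage genes 3 higher and 1 lower of 32 (0.333). Cell cycle genes had 3 higher and 10 lower of 52 (0.245), with the proliferation marker MKI67 at 0.85 (SE 0.14) and the replication gene MCM2 at -0.71 (SE 0.11). The unfolded protein list had 2 higher and 8 lower of 32 (0.126), with the cystine transporter gene SLC7A11 at -1.51 (SE 0.14). The hypoxia list had 5 higher and 7 lower of 37 (0.777), the p53 targets 6 and 5 of 29 (0.966), antigen presentation genes 1 and 4 of 22 (0.333), integrins and laminins 4 and 5 of 34 (0.94) and chemokines 2 and 3 of 35 (0.966). Metastasis suppressors had 2 and 3 of 25 (0.966), ribosomal protein genes 1 and 2 of 48 (0.799) and immediate early and heat shock genes 4 and 2 of 33 (0.333).

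With the replicate block the HTB56 counts higher and lower were 5 and 5 for HOX genes, 12 and 15 for other developmental factors, 6 and 1 for cancer-testis antigens, 4 and 2 for lung lineage genes and 7 and 16 for cell cycle genes. They were 1 and 7 for antigen presentation, 5 and 4 for chemokines, 4 and 5 for metastasis suppressors, 4 and 5 for ribosomal proteins, 7 and 2 for immediate early and heat shock genes and 1 and 2 for endothelial markers.

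Markers of other cell types moved in both directions in HTB56. Fibroblast markers had 4 higher and 1 lower of 14 (camera adjusted p = 0.133), with COL1A1 at 1.41 (SE 0.11), LUM at 1.77 (SE 0.24) and FBLN1 at -0.68 (SE 0.12). Leukocyte markers had 2 higher and 1 lower of 19 (0.728), with LYZ at 1.67 (SE 0.18) and LAPTM5 at -2.25 (SE 0.19), and endothelial markers 0 higher and 2 lower of 14 (0.94). DIAPH2 read 6.69 ± 0.08 in H0R, 3.27 ± 0.08 in H3R and 7.03 ± 0.07 in A0R. Several called genes lay in runs of chromosomal neighbours that shifted together in HTB56: 13 such runs held 440 genes, of which 235 were called in the direction of their run. CHGB and GPC6 stood at the ends of 2 runs and moved against them.

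**Figure D2:**
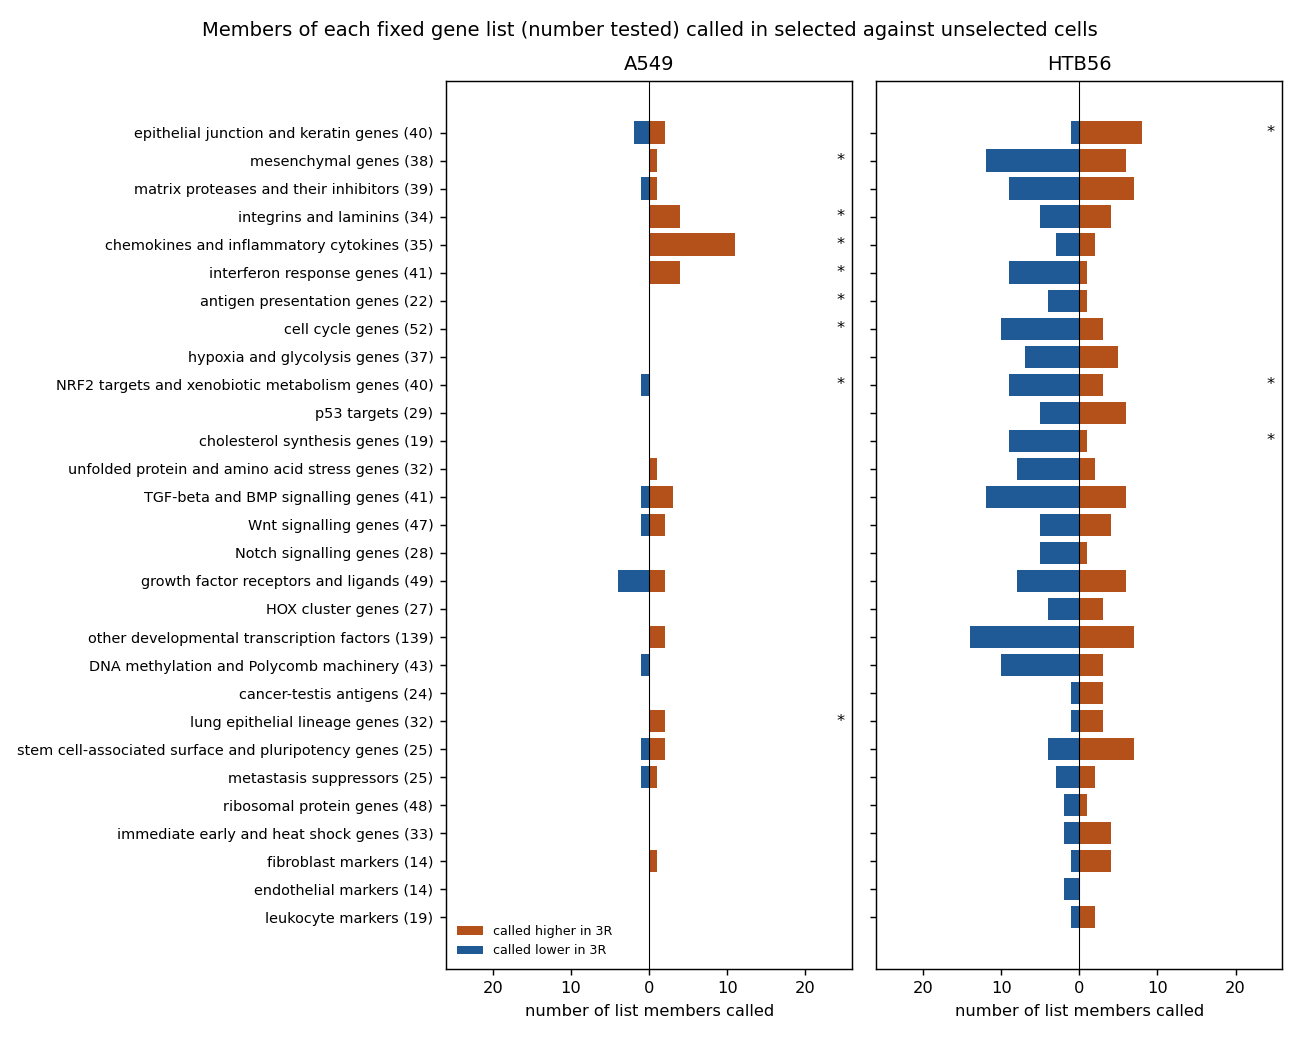
Bars give the number of members of each fixed gene list called higher (right) or lower (left) in selected cells, for A549 and HTB56, with the number tested in brackets and * for a camera adjusted p below 0.05. The chemokine list has 11 members higher and 0 lower in A549, and 2 higher and 3 lower in HTB56.

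The difference of the 2 selection changes was tested directly. For 1992 genes the log2 change differed between the lines, 877 with a higher value in HTB56 and 1115 with a lower one, and 3392 with the replicate block, 1596 and 1796. SCG3 changed by -0.01 in A549, a difference of -5.05 (limma adjusted p = 2.78e-11), NTS by 0.05 in HTB56, a difference of 4.25 (adjusted p = 9.99e-06), and PCDHB3 by -0.18 in A549, a difference of 4.29 (adjusted p = 4.5e-08). SCG3 read 3.27 to 3.33 in A0R, under the 20th percentile of 3.48, and NTS 3.51 to 3.83 in H0R, so a fall of either could hardly be seen there. How far these 2 differences follow from that baseline was not tested. Of the 20 largest falls, 18 started too low in the other line for an equal fall to stay above that percentile, with ADGRL2 and DIAPH2 the exceptions. CXCL1 rose in A549 and fell by 0.95 in HTB56, a difference of -2.62 (adjusted p = 2e-06). Of the interferon list, 13 of 41 genes had a lower change in HTB56 and 1 a higher one, 17 and 1 over the list alone (camera adjusted p = 3.19e-06, and adjusted p = 0.0145 with an estimated correlation). IFI44L, an interferon-induced gene, changed by 0.09 in A549 and -1.40 in HTB56 (difference -1.48, adjusted p = 7.82e-05).

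The chemokine list differed likewise, with 10 lower and 2 higher of 35 (camera adjusted p = 0.00014), as did the mesenchymal list with 12 lower and 3 higher of 38 (0.0183) and the integrin and laminin list with 7 lower and 1 higher of 34 (0.0256). The epithelial list had 9 higher and 3 lower of 40 (0.0261), with DSP at a difference of 2.75, the cholesterol list 4 lower and 1 higher of 19 (0.0261), and the unfolded protein list 9 lower and 1 higher of 32 (0.0293; 0.0628 with the block). These 6 calls were lost with an estimated correlation, at adjusted p = 0.109, 0.109, 0.186, 0.109, 0.786 and 0.568 in the order given. For the mesenchymal and epithelial lists that correlation was 0.00411 and 0.00375, under the preset 0.01. A higher correlation therefore did not end the calls of these lists. With the block the antigen presentation list was called as well, at camera adjusted p = 0.0449. Without the block its camera adjusted p was 0.0945, and 0.708 with an estimated correlation. The counts higher and lower with the block were 2 and 9 for integrins and laminins, 1 and 7 for cholesterol and 3 and 10 for the unfolded protein list. The epithelial call was lost without A0R replicate 3 (0.0581), A3R replicate 1 (0.0632), H0R replicate 1 (0.0533) or H3R replicate 3 (0.0568), and the integrin and laminin call without A0R replicate 3 (0.067) or H0R replicate 2 (0.0646). The cholesterol and unfolded protein calls were lost without A0R replicate 2 (0.0556 each), A0R replicate 3 (0.0875 and 0.0624), A3R replicate 1 (0.165 and 0.142), H0R replicate 2 (0.171 and 0.103) or H3R replicate 3 (0.0568 and 0.118). Of the 7 lists, 3 were called without A0R replicate 3, and 4 without A3R replicate 1, H0R replicate 2 or H3R replicate 3.

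A small set of genes changed the same way in both lines. HAS2, which encodes a hyaluronan synthase, rose by 1.48 (SE 0.25) in A549 and 1.46 (SE 0.25) in HTB56 (limma adjusted p = 0.00595 and 0.000768). CPS1, the urea cycle enzyme carbamoyl-phosphate synthetase, rose by 1.33 and 2.11, RNF144B by 1.02 and 1.67, TBXAS1, which encodes thromboxane synthase, by 1.31 and 0.87, ABLIM3 by 0.96 and 0.90, and PRICKLE2 by 0.86 and 1.12. THSD7A changed by -1.17 and -1.70, ADAMTS9, a matrix protease gene, by -1.40 and -0.79, AMOTL1 by -0.72 and -1.57, CXXC5 by -0.56 and -2.14, and PPARGC1A, a coactivator of mitochondrial gene expression, by -1.12 and -0.56. The other leading genes were TFF1, TSPAN8, HPGD and FRMD5, higher in both, and PDK4, TMT1B, MGLL, IGF2BP3 and TRIM2, lower in both. Their A549 calls were less stable, lost under 4 (TFF1, PDK4) to 13 (MGLL) of 24 alternatives.

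In all, 25 genes were higher in both selected lines, where independent lists would share 13.56, and 21 were lower in both, where they would share 13.75. The 46 genes became 111 with the replicate block, 51 higher and 60 lower, and 23 without A0R replicate 1 or A3R replicate 2, 24 without A0R replicate 2 and 25 without A3R replicate 1. Another 37 genes were higher in A549 and lower in HTB56 (17.24 for independent lists) and 12 the reverse (10.81), and the change of all 49 differed between the lines. CXCL8, which encodes a neutrophil chemokine, rose by 1.48 in A549 and fell by 1.54 in HTB56 (difference -3.02, adjusted p = 1.54e-05), DNAJC12 changed by 1.46 and -1.32 and LXN by 1.11 and -1.16. LIN28B, which encodes an RNA-binding protein that blocks let-7 processing, changed by -0.83 in A549 and 1.48 in HTB56 (difference 2.32, adjusted p = 6.61e-07), SH3BGRL2 by -1.14 and 0.71, and ALDH2 by -0.69 and 0.72. Across the 16922 genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of 0.00835 and a Spearman correlation of 0.0121. With 46 genes called alike and 49 in opposite directions, the shared calls show no preference for the same direction either.

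**Figure D3:**
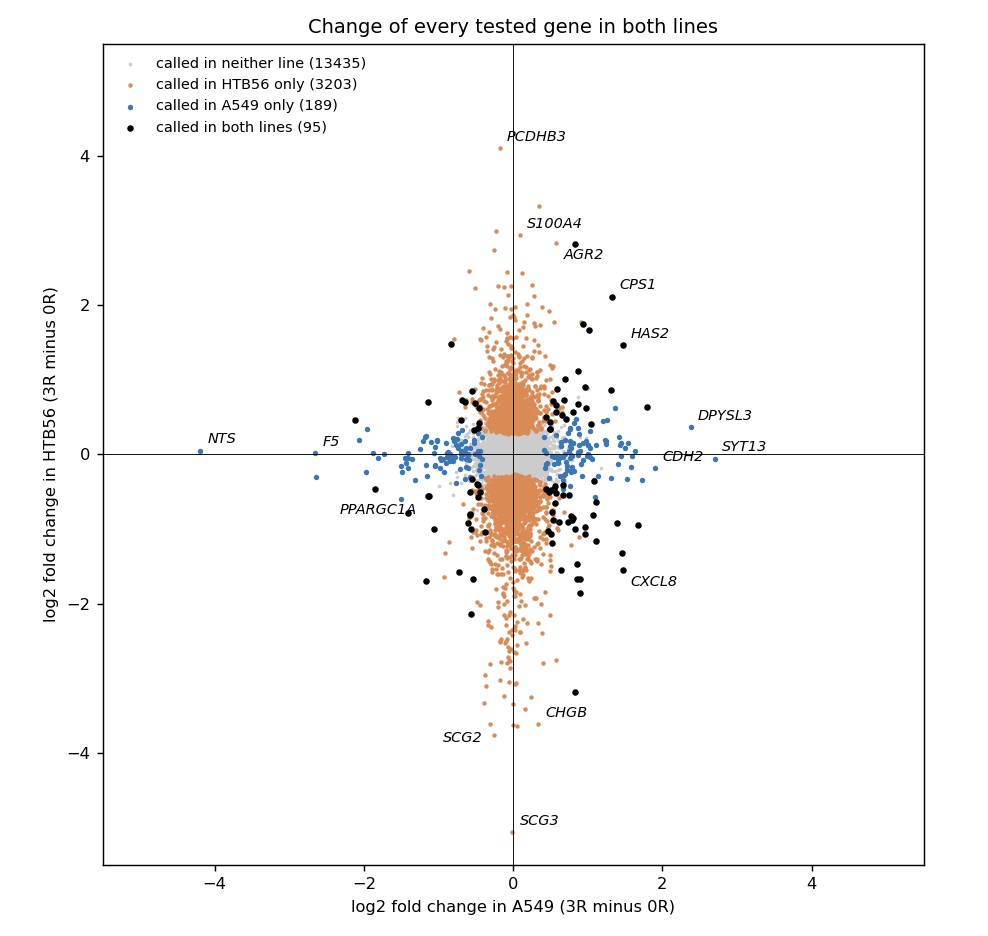
Each point is a gene, with its log2 fold change (3R minus 0R) in A549 on the horizontal axis and in HTB56 on the vertical axis, coloured by the line in which it was called. The 95 genes called in both lines lie in all 4 quadrants, and the vertical spread exceeds the horizontal one, from -5.06 to 4.11 against -4.20 to 2.70.

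The unselected lines were compared to set the scale of these changes. HTB56 stood far above A549 for FABP4, a fatty acid carrier gene (log2 difference 7.02, SE 0.64), SLC14A1, a urea transporter gene (6.58, SE 0.65), and SCG3 (5.66, SE 0.10). A549 stood above HTB56 for KYNU, an enzyme gene of tryptophan breakdown (HTB56 minus A549 -6.25, SE 0.21), CP, the ceruloplasmin gene (-6.17, SE 0.22), CYP24A1, which encodes the vitamin D 24-hydroxylase (-5.91, SE 0.28), and AKR1B10, an aldo-keto reductase gene (-5.76, SE 0.31). Further genes higher in HTB56 were IGFBP5 (5.88), IL7R (5.85), LAMA4 (5.78), COL6A3 (5.76), SCG2 (5.69), SHISA3 (5.62) and TNFRSF11B (5.54), and further genes higher in A549 were HGD (-6.02), TM4SF20 (-6.00), RSPO3 (-5.98), HAVCR1 (-5.96), SLCO1B3 (-5.84) and CD24 (-5.75). SCG3 and 2 A0R arrays of FABP4 lay below the 20th percentile of 3.48 in A549, as did SLCO1B3 and CD24 in HTB56, so the size and order of these log2 differences depend on background. In all 7638 genes differed at a limma adjusted p below 0.05, 4212 higher and 3426 lower in HTB56, and 2350 at least 2-fold. FABP4, SLC14A1 and COL6A3 had wide spreads in unselected A549 (SD 2.03 and 2.06 for the first 2), because A0R replicate 2 read 6.24, 7.69 and 6.80 where the other A0R arrays read 2.47 to 4.59. Without that array the differences were 8.18, 7.77 and 6.61, those of IGFBP5 and IL7R 6.50 and 6.47, and 6977 genes differed. Without A0R replicate 1 those of FABP4 and SLC14A1 were 6.30 and 5.94.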

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

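The tests of mixed cells, mouse cells, handling, leukocytes and shared batches in this part were chosen only after the result was seen, and so was the reading of the A549 neighbour search as undecided. Groups of 3 arrays are too small for a test of single outlying arrays. A difference of the selection change between the lines, tested by limma, drew attention to the results here. Values are the log2 change in HTB56 minus that in A549. The 50 leading named genes were chosen for large changes in 1 line or for opposite calls, so a difference between lines nearly follows from that choice. Of 147 other named genes 101 differed. These were mainly named for a call in at least 1 line, so this share is raised by the choice. Among all 16922 genes tested, 1992 differed (11.8%). For genes that rose in A549 the differences were SYT13 -2.76, DPYSL3 -2.02, CDH2 -2.09, TNFSF15 -1.15, GASK1B -2.07, CXCL1 -2.62, EFEMP1 -1.60, SERPINA3 -1.61, CXCL5 -1.75 and FAM133A -1.38. For genes that fell in A549 they were NTS 4.25, F5 2.67, LIN7A 2.33, SCN9A 2.59, SLC17A3 2.26, NPY1R 1.74, SLPI 2.30, FGB 1.90, ADGRL2 1.39 and ADH6 1.76.

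For genes that rose in HTB56 the differences were PCDHB3 4.29, PCDHB2 2.98, DIO2 3.22, S100A4 2.84, AGR2 2.25, TSPAN8 1.99, COLEC10 3.00, GPC6 3.05, CD96 2.53 and NRK 2.31. For genes that fell in HTB56 they were SCG3 -5.05, RAB3C -3.51, MFNG -3.69, FSTL5 -3.63, CHGB -3.95, SCG2 -3.30, DIAPH2 -3.58, TMEM145 -3.35, UGT8 -2.95 and NSG2 -3.49. Of the 20 genes that fell, 18 started too low in the other line for an equal fall to stay above the 20th percentile, the exceptions being ADGRL2 and DIAPH2. This limits the fall of these 18 that could be seen there. Their distance above the percentile ranged from -0.588 (ADH6) to 2.49 (TMEM145), so a smaller fall could be seen for some. How far each difference follows from the baseline was not tested. Genes called in opposite directions gave CXCL8 -3.02, DNAJC12 -2.78, LXN -2.27, KCNN4 -1.94, STC1 -2.02, LIN28B 2.32, SH3BGRL2 1.85, ALDH2 1.41, PPP1R14A 1.34 and RBPMS 1.39. The A549 call was lost for STC1 without A0R replicate 1 (adjusted p = 0.0651) or 2 (0.132) or A3R replicate 1 (0.1), 2 (0.0727) or 3 (0.0741). It was lost for KCNN4 without A0R replicate 3 (0.0564) or A3R replicate 1 (0.0725) or 2 (0.0561), and for RBPMS without A0R replicate 1 (0.143) or 3 (0.0751) or A3R replicate 1 (0.095), 2 (0.0561) or 3 (0.0994). The median difference was 0.15 for epithelial junction genes, -0.22 for mesenchymal genes, -0.23 for integrins and laminins, -0.34 for chemokines, -0.33 for interferon response genes, -0.24 for cholesterol synthesis genes and -0.0930 for unfolded protein genes. Of 9858 probe sets without a gene name here, 13 were called in A549 and 238 in HTB56, a signal in data outside the named genes.

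The rise of S100A4, AGR2 and epithelial junction genes in selected HTB56 cells was set against admixed cells. A549 cells are argued against by the 6 genes bright in A549 and dim in unselected HTB56, whose upper quartile of change was -0.0244. Mouse cells stay open: 58 stromal, blood and mature lung markers had a median of 0.0699, but the 14 fibroblast markers had an upper quartile of 0.587, with LUM at 1.77 and COL1A1 at 1.41 (camera adjusted p = 0.133, fry adjusted p = 0.0112), while the 11 mature lung markers had quartiles of 0.03 and 0.12 with 0 called, and the binding of mouse RNA to human probes was not calibrated. Each replicate number occurs once in every group, so the block leaves the changes as they are, and its 12 epithelial genes called higher against 8 test no batch. A change of the cells during selection also stays open, beside culture differences that the labels do not give.

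The rise of chemokine genes in selected A549 cells was set against handling and leukocytes. Immediate early and heat shock genes had a median change of -0.00691 (quartiles -0.17 and 0.05), and leukocyte markers of -0.0464 (quartiles -0.14 and 0.13). Both medians lie below the chemokine median of 0.29 by more than these spreads, and LYZ and LAPTM5 read 3.54 and 4.87 in A0R and changed by 0.08 and 0.05, which argues against mouse leukocytes, as far as mouse RNA binds these probes, and against stress that acts on these genes at harvest. The replicate block, with 13 chemokine genes called higher against 11, tests no batch, as above. Stress that had passed by harvest, culture density, which is not given in the sources used here, and a change of the cells during selection stay open.

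Runs of neighbouring genes shifted together in selected HTB56 cells, 7 upward and 6 downward, for example 55 genes from CHGB to XRN2 (median of expressed genes 0.82) and 70 genes from CYP2U1 to RAB33B (-0.49). Chance order is argued against by the highest window median, 0.832, against 0.477 at most in 1000 shuffles, and noise of single arrays by runs found on arrays 1 and 2, whose median change on arrays 3 was 0.934 times as large. Of the expressed genes 91.6% moved with their run, and 90.1% of 303 did so on arrays 3 in the runs found on arrays 1 and 2. Runs were chosen by a high median of neighbours, so most of their genes had to move. These shares therefore do not test regulation of a few genes per run, and arrays 3, from the same groups, test only array noise. Regulation of whole neighbourhoods stays open, and another candidate explanation is a gain or loss of DNA copies in the selected line, which was not tested on DNA. In A549 the highest window was 0.254, reached by 1 of 1000 shuffles, with 0 runs. A run needed a window above the highest shuffle, here 0.258. The 0 runs therefore do not show that neighbours shifted independently in A549, and the question stays undecided.

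Other splits of the arrays were counted for each comparison. With 10 splits of 6 arrays a share under 0.05 cannot arise. The grouping by selection gave 284 genes in A549 (highest other split 3), 3298 in HTB56 (0) and 7638 between unselected lines (0), and each was reached by 1 split. For gene lists it gave 8 in A549 (highest other 10, 2 splits as high) and 3 in HTB56 (11, 5 splits as high), counting the grouping by selection itself. Chance is not excluded for either number of lists. Of 100 splits within both lines, 1 gave as many as the 1992 genes that differ between lines (highest other 1918) and 1 as many as the 46 genes shared (highest other 1). Of all 32 splits that part every pair of equal number, counted only after the result was seen, 2 gave as many in each case, so chance is not excluded for either count. The other of the 2 swaps selected and unselected arrays in 1 line and gave 2127 and 49, the 49 being the genes called in opposite directions, and the highest of the rest was 1412 and 0. The split with 1918 kept the HTB56 arrays grouped by selection and regrouped A549, and leaving out 1 array gave 1514 to 1942, so the 1992 rest mostly on the HTB56 change. For the 7 lists that differ, 25 of 100 splits gave as many (highest other 11), so chance is not excluded. Among the splits counted in each line that part as many pairs, the highest others were 0 genes in A549, HTB56 and between unselected lines and 4 lists in A549 and HTB56.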

How the results depend on the processing

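Leaving out all 4 arrays numbered 3 and the block shared by both lines were chosen only after the result was seen. No called result changed its direction under any alternative. Counts below are of genes in A549, HTB56, their difference and both lines alike (reported 284, 3298, 1992 and 46), and of gene lists in A549, HTB56 and their difference (8, 3 and 7). Fitting only the 6 arrays compared gave 172 in A549 and 26 in both. The replicate block gave 526, 3392 for the difference and 111 in both, and the shared block 546, 3447 and 117. Among the 257 named-gene values the block ended the call of HPGD in A549 (adjusted p = 0.0579) and added that of EZH2 in HTB56 (0.0362), and among list calls it changed only the 3 named in the report. Array weights gave 72 in both. A threshold of 0.01 gave 133, 2041, 1027 and 13. The treat test gave 95, 1190, 811 and 7, and 4704 between unselected lines (reported 7638). Filtering at the median gave 5 lists in A549, and testing every probe set 5 in A549 and 5 in HTB56. An estimated correlation gave 4, 0 and 1 lists, and fry 5 and 13. The stricter threshold and treat call fewer genes by construction, and the cause of the other changes was not tested. Leaving out 1 array gave 167 to 275 genes in A549, 2494 to 3433 in HTB56, 1514 to 1942 for the difference, 6695 to 7792 between unselected lines and 23 to 39 in both, and 6 to 13, 2 to 4 and 3 to 8 lists. Without the doubted A0R replicate 2 they were 174, 3241, 1683, 6977 and 24 genes and 10, 3 and 5 lists. Without arrays numbered 3 they were 268, 3072, 1773, 7533 and 36 genes and 6, 4 and 7 lists. For the 257 named-gene values, 5901 alternative values were the same, 243 weaker, 2 stronger, 12 moved and 0 reversed. Dim genes near background have compressed changes, which RMA values cannot undo.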

Other observations

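In this part the lists of secretion and protocadherin genes and the gene sets of the other line were drawn up after the leading genes had been seen, and the tests of RNA from the other line were chosen only after the result was seen. In HTB56 the loss of SCG3 and CHGB extended to other genes of regulated secretion, here named after their values were seen. Of 46 genes listed for regulated secretion, among them general neuroendocrine genes such as NCAM1 and ENO2, 22 were called lower in H3R and 2 higher. This count includes members that had already been seen to fall. Of the 35 members not seen beforehand, 11 were lower and 2 higher. CHGA, the chromogranin A gene, fell by 3.08 (SE 0.22, limma adjusted p = 2.02e-07), SYP, the synaptophysin gene, by 3.02 (SE 0.15), UNC13A, a vesicle priming gene, by 2.65 (SE 0.16), CPLX1 by 2.64 (SE 0.11), PTPRN by 2.38 (SE 0.14) and STX1A by 2.29 (SE 0.16). RAB3B (1.13, SE 0.17) and SYT1 (0.73, SE 0.12) rose, while INSM1 changed by 0.09 and UCHL1 by -0.13 with adjusted p of 0.715 and 0.741. In A549 the same 46 genes had a median change of -0.02.

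A fall of this group beyond its leading members is one hypothesis for HTB56. The 35 members not seen beforehand had a median change of -0.18, with 11 lower and 2 higher (camera p = 4.95e-05, and p = 0.00545 with an estimated correlation). The median did not reach the bound of -0.2 set beforehand, so the test leaves open whether the whole group fell or a part of it. A rise of the protocadherin beta cluster as a whole was the hypothesis for PCDHB2 and PCDHB3. The other 13 members had a median change of 0.0884 (quartiles -0.08 and 0.57), with 4 higher and 1 lower (camera p = 0.0263, and p = 0.139 with an estimated correlation), among them PCDHB13 at 1.46, PCDHB14 at 1.32 and PCDHB8 at 1.30. The median lay under the bound of 0.2 set beforehand, so by that bound the hypothesis of a rise of the cluster as a whole failed. The spread of the members was not part of that bound and was considered in addition. With an upper quartile of 0.57, a rise of a part of the cluster stays open.

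One array of unselected A549, A0R replicate 2, may hold a trace of RNA from selected HTB56 cells. The 28 genes bright in both HTB56 groups and dim in A549 lay above the A549 median on it by a median of 0.84 (quartiles 0.46 and 1.35), 20 of them by over 0.5, and the 21 that were not among the named genes by 0.66, whereas 3542 genes dim in both lines lay at 0.00. FABP4 and SLC14A1 were each higher by 3.17, IL7R by 1.60, TLR4 by 1.22 and SPARC by 1.04. RNA of unselected HTB56 cells as the source is argued against by 12 genes bright in H0R and at least 4-fold lower in H3R, among them SCG2, SCG3 and CDH11, whose median excess was 0.0931. On a linear scale the excess came to a median of 2.61% of the signal in H3R, a rough figure because RMA compresses dim signals. Whether RNA, labelled target or cells were mixed cannot be read from the arrays, and a culture of HTB56 outside this series stays open as a source.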
